A study of Mus musculus with 2 samples.

How the data were processed

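The series holds 2 droplet-based single-cell RNA libraries of mouse group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that make type 2 cytokines. The first was made from lung and the other from skin of C57BL/6 mice at postnatal day 14. Per the labels, the mice carried reporter alleles of Arg1, Il5 and Il13, and the cells were sorted as lineage-negative, CD45-positive and positive for Red5, the Il5 reporter. The sorted cells went through the Chromium Single Cell 3' v2 kit on the same day. The labels do not say how many mice each library pooled. The sort sets which cells enter the libraries. Whether the reporter alleles alter the 3' tags counted for Il5, Il13 and Arg1 was not examined, and the levels of these genes are those of the tags assigned to them.

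The deposited values are raw UMI counts per gene and barcode, where a UMI (unique molecular identifier) marks an original RNA molecule. Per the submitters' processing notes, the authors used Cell Ranger and the mm10 genome build. The version of Cell Ranger, the gene annotation and the cell calling are not given in the sources used here. Each table lists 27998 genes by Ensembl ID and symbol, and symbols are used as the tables give them. Gene positions were looked up by Ensembl ID in the GENCODE M21 annotation of GRCm38, the assembly named mm10, and 101 of the 101 named genes matched.

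Cells with at least 500 genes detected and at most 10% mitochondrial UMIs were kept. This left 6304 of 6348 lung barcodes (13 failed for few genes and 31 for mitochondrial UMIs) and 3000 of 3030 skin barcodes (2 and 28). Each library was clustered by itself with scanpy 1.11.5 and leidenalg 0.10.2. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 0.8 with a fixed seed were used. Clusters carry numbers. A cluster was called ILC2-like or another type only from marker lists fixed before the data were examined. The thresholds of the naming rule were set after the clusters had been seen. A marker counted as detected in at least 20% of a cluster's cells, and another type's marker also had to be at least 4-fold above the rest of the library. At least 3 markers were needed, and clusters whose 10 leading genes held another type's markers but none of ILC2s stayed unnamed. Clusters of unnamed cells held 44.5% of the compared lung cells and 28.9% of the compared skin cells, and they were kept in the comparison. Clusters named as another type were left out, with 30 lung cells (endothelial-like) and 81 skin cells (33 endothelial-like, 25 keratinocyte-like and 23 fibroblast-like). The left-out lung cluster was named by 9 endothelial markers, but its leading genes also included a gene of airway club cells, Cbr2, chosen after its values were seen, and it is treated as a mixture.

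Doublets were kept in the main comparison. Scrublet, as provided in scanpy, called 0 of 6304 lung cells and 1 of 3000 skin cells, so its automatic threshold did not work here. As an alternative, the cells with the highest scores were left out at an expected rate of 0.8% per 1000 cells, which removed 318 lung and 72 skin cells.

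With 1 library per tissue no test was possible and no p-value, standard error or count of tested genes is given. UMI counts were summed over the compared cells of each library and given as CPM, the usual scaling of a gene's UMIs by the total of the library, with exact Poisson intervals. The ratio of skin CPM to lung CPM has an exact conditional binomial (Clopper-Pearson) interval. Except where stated, intervals are at 95% and cover counting error only. No interval covers the spread between animals, sorts or libraries. A gene was called higher in a library by a rule of size, at least 2-fold apart and at least 50 CPM in the higher library. A gene with no UMI in a library was set to a floor of 3 counts there. In total 22 gene lists were described by their members past the rule of size and by the median log2 ratio of members with at least 10 CPM in either library. That median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The lists overlap, so their results are not independent. The share of cells with a UMI of a gene was computed after thinning each cell to 3000 UMIs, which left out 692 lung and 248 skin cells with fewer. Co-detection of gene pairs was described by the odds ratio in the same thinned cells.

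The gene lists, filters, rule of size, main design and most alternatives were fixed before the data were examined. The named genes were chosen by a rule fixed then. They are 16 key genes, the 10 genes with the largest ratio in each direction among those past the rule of size, and up to 4 members per list with the largest absolute ratio among members at 50 CPM or more. For each cluster the 5 leading genes at 100 CPM or more were added. Mitochondrial, ribosomal protein, sex-linked, globin and antigen receptor genes and gene models without a name were not eligible for the 10 largest ratios. Of the genes the rule picks, 2 are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

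Alternatives were no filter or stricter filters on cells (1000 genes and 5% mitochondrial UMIs), other types kept, only ILC2-like clusters, no cells with high doublet scores, and no cells with a UMI of Mki67, Top2a, Cdk1, Ube2c or Birc5. Others changed the scaling, the weight of each cell, the CPM minimum, the thinning depth, the clustering resolution and seed, or the genes used for clustering. Leaving out skin cluster 3 was added after seeing the data. The summation, intervals, list percentiles and clustering were tested on simulated data for the comparison of lung with skin. Of 200 genes changed 4-fold among 2664 simulated, 100% of those set higher and 99% of those set lower were recovered, with 0 unchanged genes called. The intervals covered the true ratio for 95.5% of genes, and 3% of 100 lists without a shift fell outside the random range. The simulated counts were drawn for each gene independently from the Poisson model that the intervals assume, and these lists were random genes. The simulation therefore checks the computation only. It does not show how often lists of genes that vary together fall outside the random range.

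The list genes Ifi213, Hbb-b1 and Hbb-b2 were not analysed here, nor were the T cell receptor and immunoglobulin constant genes of the marker lists. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.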

Results

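Single-cell RNA profiles of ILC2s sorted from lung and from skin of 14-day-old mice were compared to ask how the same lymphocyte type differs between these tissues shortly after birth. There was 1 library per tissue. The lung library held 28685213 UMIs in 6348 barcodes and the skin library 17878724 UMIs in 3030 barcodes. Among cells that passed the filters the median was 4063.5 UMIs and 1603 genes per cell in lung and 5164 UMIs and 1721 genes in skin. After cells of other types had been left out, 6274 lung cells with 28373165 UMIs and 2919 skin cells with 16784854 UMIs were compared. Without replicate libraries, every difference below describes these 2 libraries and not the tissues, and intervals are 95% counting intervals except where stated.

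The cytokine genes Il5 and Il13 were higher in skin and Arg1 was higher in lung. Il5, the eosinophil growth factor, stood at 1212 CPM (1195 to 1229) in skin and 66.1 CPM (63.2 to 69.2) in lung, an 18.3-fold difference (17.5 to 19.2). Il13, which drives mucus production and alternative macrophage activation, was 2.72-fold higher in skin (2.64 to 2.80), at 751 against 276 CPM. Arg1, the arginine-degrading enzyme arginase, went the other way and was 7.59-fold higher in lung (6.84 to 8.45), at 173 against 22.8 CPM. Areg, the growth factor amphiregulin, was under 2-fold apart, at 1851 CPM in skin and 1199 CPM in lung.

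Receptors for cytokines that activate ILC2s differed in both directions or were alike. Il1rl1, the receptor for IL-33, was 3.17-fold higher in lung (3.03 to 3.32), at 427 against 135 CPM. The skin value was uneven, as Il1rl1 ranged from 14.9 CPM in its lowest compared skin cluster to 621 CPM in skin cluster 4. The highest compared lung cluster stood at 551 CPM. Il17rb, part of the receptor for IL-25, was 3.69-fold higher in lung, at 95.1 against 25.7 CPM. Il18r1, the receptor for IL-18, was 9.52-fold higher in skin (8.74 to 10.4), at 207 against 21.8 CPM. Crlf2, part of the receptor for TSLP and chosen after its values were seen, was under 2-fold apart, at 111 CPM in lung and 123 CPM in skin. Klrg1, an inhibitory receptor of mature ILC2s, was 4.26-fold higher in lung, at 197 against 46.4 CPM. The co-stimulatory receptor Icos was 7.12-fold higher in skin (6.93 to 7.31), at 1620 against 228 CPM. Tcf7, a transcription factor of early innate lymphoid development, was 4.84-fold higher in skin (4.33 to 5.42), and Mki67, a marker of dividing cells, 2.51-fold higher. Gata3, the transcription factor that sets ILC2 identity, was 1.92-fold higher in skin, just short of the rule of size, and Il2ra and Il7r were also under 2-fold apart. Zbtb16 and Ctla4 stayed below 50 CPM in both libraries.

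Among these genes Il5 (ENSMUSG00000036117) lies on chromosome 11 of GRCm38 from 53720794 to 53725106 on the plus strand, and Il13 (ENSMUSG00000020383) on the same chromosome from 53631324 to 53634702 on the minus strand. Arg1 (ENSMUSG00000019987) lies on chromosome 10 from 24915221 to 24927484. The neighbouring receptor genes Il1rl1 (ENSMUSG00000026069) and Il18r1 (ENSMUSG00000026070) lie on chromosome 1 from 40429570 to 40465415 and from 40465552 to 40500854, and they differed in opposite directions. Icos (ENSMUSG00000026009) lies on chromosome 1 from 60977927 to 61000320. All are annotated as protein-coding, and the counts are per gene.

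The 10 largest ratios toward skin included several surface receptors. The chemokine receptor Ccr6 stood at 92.2 CPM in skin and 0.32 CPM in lung, a ratio of 291 (153 to 636). Its log2 ratio of 8.18 was 6.53 with only ILC2-like clusters, since skin cluster 2, which held it at 247 CPM, stayed unnamed. The transcription factor Ovol2 stood at 65.5 against 0.18 CPM and the junctional adhesion gene Amica1 at 177 against 0.85 CPM. The lymph node homing receptor Ccr7, the tetraspanin Cd9, the activating receptor Klrk1, the integrin Itgae, which binds epithelial E-cadherin, and the actin-bundling gene Palld were between 28.3-fold and 55.7-fold higher in skin. Sfn, an epithelial 14-3-3 protein, was 41.6-fold higher in skin, and it also stood at 3008 CPM in the left-out skin cells against 59.9 to 375 CPM over the compared skin clusters. Cd9 stood at 1500 CPM in those left-out cells.

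Toward lung, the mast cell carboxypeptidase Cpa3 was 76.4-fold higher (53.4 to 113), at 136 against 1.79 CPM. The protease inhibitor Serpina3g, the matrix gene Podnl1, the GABA transporter Slc6a13, the tetraspanin Tspan13 at 567 against 28.8 CPM, and the scavenger receptor Stab2 at 387 against 22.7 CPM followed. The small lymphocyte GTPases Gimap1, Gimap3 and Gimap6 were between 16.9-fold and 20.2-fold higher in lung. Scgb1a1, the secretoglobin of airway club cells, had 0 UMIs in skin and 135 CPM in lung, with a lower bound of 613-fold on the ratio. It stood at 123996 CPM in the left-out lung cluster and between 82.6 and 154 CPM in the compared lung clusters.

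Of 3099 genes with at least 50 CPM in either library, 357 were higher in skin and 337 higher in lung by the rule of size, and 116 and 61 of these were at least 4-fold apart. Across genes, which are not independent replicates, the log CPM of the libraries correlated with a Pearson r of 0.789. The median log2 ratio over these genes was -0.10. Relative to it the log2 ratio was 4.30 for Il5, 1.55 for Il13, -2.82 for Arg1, -1.56 for Il1rl1, 3.35 for Il18r1 and 1.05 for Gata3, which then passed 2-fold. With totals that leave out mitochondrial and ribosomal protein genes the counts were 416 higher in skin and 528 higher in lung, and centred on the median ratio they were 406 and 276, so which library had more such genes depends on the scaling.

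**Figure D1:**
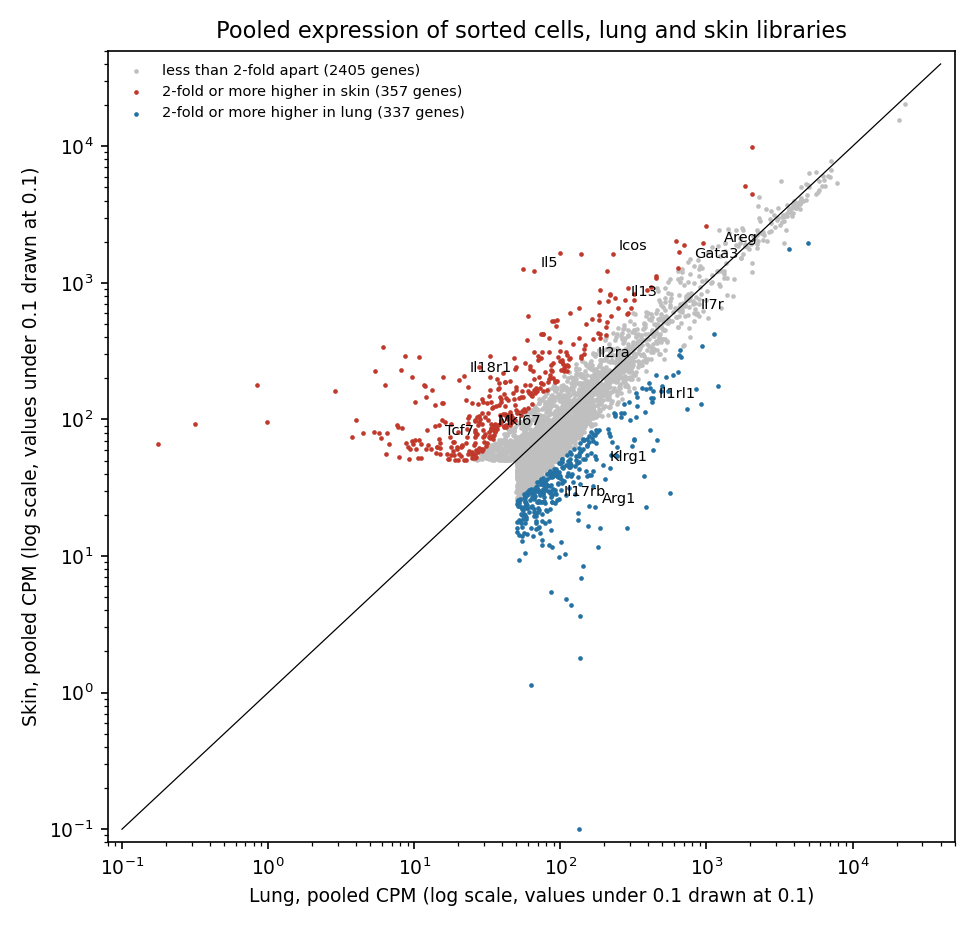
Each point is a gene with at least 50 CPM in either library, with its pooled lung CPM on the horizontal axis and its pooled skin CPM on the vertical axis, both on log scales with values under 0.1 drawn at 0.1, and the line marks equal CPM. The 357 genes in red lie at least 2-fold above the line, among them Il5, Icos and Il18r1, and the 337 genes in blue at least 2-fold below it, among them Arg1, Klrg1 and Il1rl1.

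Among type 2 effectors, 3 of 19 measured members were higher in skin, including Il5 and Il13, 4 were higher in lung, including Arg1, the cytokine Lif (3.27-fold) and the chemokine Ccl5 (2.79-fold), and 12 were neither. The median log2 ratio was 0.35 against a random range of -0.41 to 0.30. This median turned to -0.31 with only ILC2-like clusters, -0.24 without skin cluster 3, -0.06 with totals lacking mitochondrial and ribosomal protein genes and -0.02 with a 50 CPM minimum for members, so the list had no settled direction. Among cytokine receptors, 11 of 27 members were higher in skin, 3 higher in lung and 13 neither, with a median of 0.73 and a random range of -0.37 to 0.21. The TNF-family receptors Tnfrsf9 (4-1BB), at 287 against 10.8 CPM, and Tnfrsf4 (OX40), at 195 against 20.4 CPM, and the receptor for IL-21, Il21r, at 90.6 against 7.58 CPM, were among the 11. Among receptors and enzymes of neuropeptides and lipid mediators, 2 of 20 were higher in skin, 4 higher in lung and 14 neither, and the median of -0.24 lay within the random range. The members of this list were far apart. Ramp3, a partner protein of the calcitonin receptor family, was 22.7-fold higher in skin (21.6 to 23.9), at 1264 against 55.7 CPM, and the adenosine receptor Adora2a 4.03-fold higher. Its relative Ramp1, a partner in the receptor for calcitonin gene-related peptide, was 5.04-fold higher in lung, at 841 against 167 CPM. The leukotriene B4 receptor Ltb4r1 was 7.12-fold higher in lung, at 924 against 130 CPM.

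Transcription factors of innate lymphoid cells leaned toward skin, with 6 of 31 higher there, 3 higher in lung and 22 neither, and a median of 0.53 above the random range of -0.41 to 0.21. Nfil3, needed for early innate lymphoid development, was 2.85-fold higher in skin beside Tcf7, and Pparg and Bhlhe40 were 3.18-fold and 2.86-fold higher in lung. Genes known from precursors or resting cells had a median of 0.89, with 4 of 16 higher in skin, 2 higher in lung and 10 neither. The 4 were Ccr7, Il18r1, Tcf7 and the chromatin organiser Satb1, which was 8.63-fold higher in skin, and Il18r1, Tcf7 and Ccr7 are also members of other lists. Of homing and adhesion genes, 7 of 23 were higher in skin, including Ccr6, Ccr7 and Itgae, 4 higher in lung and 12 neither, with a median of 0.55. Ccr2, a chemokine receptor of inflammatory recruitment, was 6.13-fold higher in lung, at 731 against 119 CPM. Of inhibitory and co-stimulatory surface molecules, 1 of 18 was higher in skin, Cd28 at 135 against 10.1 CPM, 1 higher in lung, Klrg1, and 16 neither. Their median of 0.39 lay above the random range of -0.49 to 0.28, and with only ILC2-like clusters, with other types kept or with a 50 CPM minimum it lay inside.

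Of genes of the NF-kB pathway, 8 of 22 were higher in skin, 2 higher in lung and 12 neither, with a median of 0.58 and a random range of -0.34 to 0.25. The subunit Rel was 9.48-fold higher in skin, at 570 against 60.1 CPM, and Cd83 8.37-fold higher, while the IkB-family genes Nfkbiz and Nfkbid were 3.02-fold and 2.90-fold higher in lung. Of immediate-early genes, which respond within minutes to stimulation and to tissue handling, 3 of 29 were higher in skin, 7 higher in lung and 19 neither. Egr1 and Jun were 7.57-fold and 7.32-fold higher in lung, and Ier3 and Dusp2 were 15.2-fold and 5.90-fold higher in skin. The median of -0.16 lay within the random range of -0.22 to 0.23, but below the range with only ILC2-like clusters or without skin cluster 3, and it was 0.09 with every cell weighted equally. Of heat shock genes, 1 of 14 was higher in skin (Hspa5, 2.23-fold), 1 higher in lung (Chordc1, 2.01-fold) and 12 neither, with a median of -0.13 inside the random range and a mean of 0.15.

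Cell cycle genes were higher in skin for a minority of members. Of G2/M genes, 6 of 37 were higher in skin, 0 higher in lung and 31 neither, with a median of 0.75 and a random range of -0.53 to 0.07, or a median of 0.22 without cycling cells. Kif23 was 4.95-fold, Cenpa 3.40-fold and Top2a 2.5-fold higher. Of S phase genes, 2 of 36 were higher in skin, Nasp and Pcna at 2.63-fold and 2.51-fold, 1 higher in lung and 33 neither. The S phase median of 0.47 turned to -0.63 without cycling cells, -0.20 with every cell weighted equally and -0.22 with cells thinned to the same depth. Of glycolysis genes, 5 of 16 were higher in skin, 1 higher in lung and 10 neither, with a median of 0.94 and a random range of -0.42 to 0.34. The lactate transporter Slc16a3 was 3.01-fold, Pgk1 2.61-fold, Tpi1 2.38-fold and Aldoa 2.25-fold higher in skin. Of lipid metabolism genes, 4 of 22 were higher in each library and 14 neither, with a median of 0.14 inside the random range, and over the alternatives the median went from -0.38 with a 50 CPM minimum to 0.40 with no minimum for members and lay above the range in 4 of 13. The triglyceride synthesis enzymes Dgat2, at 98.4 against 4.02 CPM, and Dgat1, at 523 against 89.8 CPM, were higher in skin, and the thioesterase Acot7 was 4.92-fold higher in lung.

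Genes of type 3 cells went both ways, with 1 of 6 higher in skin (Ccr6), 2 higher in lung and 3 neither. The lymphotoxin gene Ltb was 6.86-fold higher in lung, at 1201 against 175 CPM, and Il17a 6.23-fold higher, at 75.3 against 12.1 CPM. The median of -0.98 and the mean of 0.30 differed in sign, and with no minimum for members the median was 0.66. Of cytotoxic and type 1 genes, 1 of 5 was higher in skin (Klrk1), 1 higher in lung (Ccl5) and 3 neither, with a median of 0.87 inside the random range of -1.05 to 0.89, though between -0.08 and 0.99 over the alternatives. Of interferon response genes, 1 of 17 was higher in skin (Isg15, 5.03-fold), 1 higher in lung (Ifi203, 2.48-fold) and 15 neither, and the median of -0.33 lay inside the random range. Of MHC class II genes, 1 of 4 was higher in skin (Cd74, 2.06-fold), 1 higher in lung (H2-Oa, 3.69-fold) and 2 neither, with a median of 0.10 and a mean of -0.16, and the median was -0.79 with only ILC2-like clusters. The sex-linked genes were under 2-fold apart, with 0 of 4 past the rule of size, with a median of 0.14 that lay between -0.03 and 0.24 over the alternatives, and the Y-linked Ddx3y stood at 96.6 CPM in lung and 122 CPM in skin. Hemoglobin genes had a median of -2.93, or -1.21 with only ILC2-like clusters, with 2 of 4 higher in lung and 0 in skin, among them Hbb-bs at 97.4 against 9.77 CPM. Of ribosomal protein genes, 1 of 82 was higher in skin (Rps27l, 2.02-fold) and 81 were neither, with a median of -0.14 just below the random range of -0.10 to 0.11 and inside it with only ILC2-like clusters. Of mitochondrial genes, 1 of 13 was higher in skin (mt-Atp8, 2.37-fold) and 12 were neither, with a median of 0.29. In all, 10 of the 22 lists had medians above the random range and 3 below it.

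**Figure D2:**
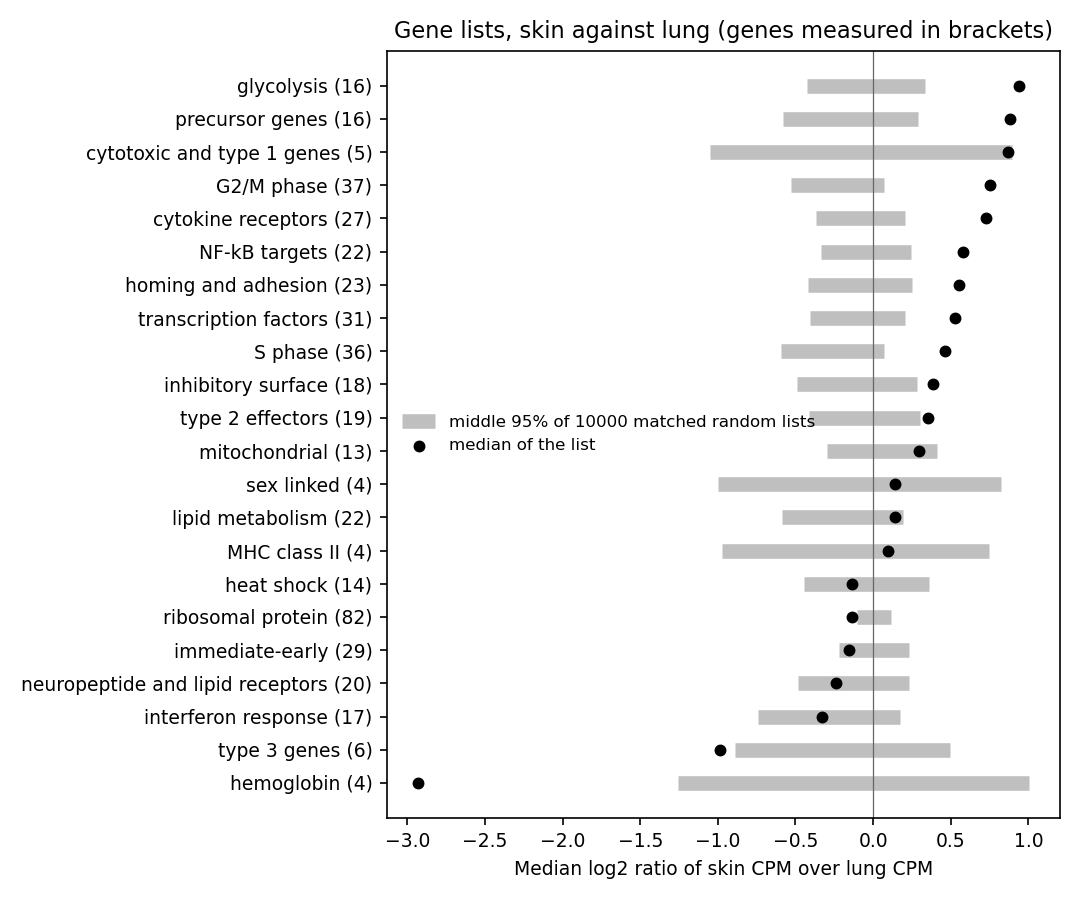
Each row is a gene list with its number of measured members, the point is the median log2 ratio of skin CPM over lung CPM, and the grey bar is the middle 95% of 10000 random lists matched on expression. The glycolysis, precursor, G2/M phase and cytokine receptor lists lie to the right of their bars, at medians of 0.94, 0.89, 0.75 and 0.73, and the hemoglobin list lies to the left at -2.93.

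The share of cells with a UMI was computed after thinning to 3000 UMIs in 5582 lung and 2671 skin cells with exact Clopper-Pearson intervals. All cells came from a sort on the Il5 reporter, and Il5 was detected in 12% of lung cells (11.2 to 12.9) and 59.5% of skin cells (57.6 to 61.4). Without thinning these shares were 16% and 67.9%. Cells of other types served as a measure of free RNA, though doublets with ILC2s were not told apart from it. Il5 was detected in 5% of 20 lung and 21.3% of 75 skin cells of other types. Their median depths before thinning were 4362.5 and 9992 UMIs, against 4062.5 and 5126 UMIs in the compared cells. Il13 was detected in 26.8% of lung and 49.9% of skin cells (31.3% and 58.5% unthinned), against 0% and 17.3% of cells of other types. Arg1 was detected in 36.1% of lung cells (34.8 to 37.4) and 5.69% of skin cells (4.84 to 6.64), or 44.2% and 8.70% unthinned. In other types its share was 5% in lung and 1.33% in skin, with an upper bound of 7.21% in skin that covers the share of the compared skin cells. Il1rl1 was detected in 68.6% of lung and 20.9% of skin cells (79.4% and 27.1% unthinned), against 20% and 1.33% in other types. Il18r1 was detected in 5.43% of lung and 42.6% of skin cells (7.87% and 57.5% unthinned), against 5% and 4%. The 5% rests on 1 of 20 cells, so by this measure the lung share of Il18r1 cannot be set apart from background. The intervals of other types, wide with 20 and 75 cells, also cover the shares of Il5, Tcf7 and Mki67 in lung and of Mki67 in skin. By level Il5 stood at 66.1 CPM in the compared lung cells against 13.9 CPM (2.87 to 40.7) in the other types, and Mki67 was gathered in the clusters set apart by cell cycle genes. Icos was detected in 40.2% and 88.8% (48.7% and 90.5% unthinned), against 10.0% and 33.3%, and Klrg1 in 35.3% and 10.2% (43.4% and 14.9% unthinned), against 10.0% and 2.67%. Tcf7 was detected in 3.91% of lung and 17.1% of skin cells (5.82% and 25.9% unthinned), against 0% and 4%. Mki67 was detected in 3.91% of lung and 9.81% of skin cells (5.45% and 13.7% unthinned), against 0% and 6.67%. Zbtb16 was detected in 0.30% of lung and 2.73% of skin cells, below its shares of 25% and 8% in other types, which therefore give no background level for it.

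Within each library Il13 and Il5 were detected together more often than independent detection would give, with an odds ratio of 1.98 (1.66 to 2.34) in lung and 2.12 (1.80 to 2.49) in skin. Of lung cells with Il13, 17.8% also had Il5, against 9.89% of those without, and of skin cells 68.5% against 50.6%. Il13 with Areg gave 1.57 in lung and 1.75 in skin, and Il13 with Klrg1 gave 1.87 and 1.5. Il18r1 and Il1rl1 were detected together less often than independent detection would give, with odds ratios of 0.59 (0.46 to 0.75) in lung and 0.54 (0.44 to 0.66) in skin. Il18r1 with Klrg1 gave 0.90 (0.70 to 1.16) in lung and 0.47 (0.35 to 0.62) in skin. Arg1 with Klrg1 gave 1.46 (1.30 to 1.64) in lung and 4.40 (2.96 to 6.46) in skin, where 30.3% of cells with Arg1 had Klrg1 against 8.97% of those without. Il13 with Il1rl1 gave 0.88 in lung and 1.75 in skin, and the lung value was 1.13 without thinning. The intervals of Il13 with Arg1 in skin, of Mki67 with Il13 in both libraries and of Il18r1 with Tcf7 in both included 1. Free RNA and depth enter these odds ratios, and differences between the libraries in them were not tested.

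The compared lung cells fell into 10 clusters and the compared skin cells into 6. In lung, the 4 clusters with most cells held 26.8%, 23.8%, 17.1% and 16.4% of the cells. Cluster 1 was set apart by Gimap3 and Txnip, cluster 2 by Il17a, Il13 and the survival gene Bcl2a1b, cluster 3 by the transcription factors Maff, Cebpb and Klf4, and cluster 4 by hemoglobin genes. Arg1 was spread over all 10, between 114 and 367 CPM, and Il1rl1 between 260 and 551 CPM, while Il13 ranged from 46.3 to 619 CPM. Cluster 5 (6.90% of cells), set apart by Tnfrsf4, Il1r2 and Ctla4, had 9 of 19 type 2 effectors at least 2-fold above the other lung cells. Cluster 6 (3.73%) held 7088 UMIs per cell at the median, and 36.8% of its cells were among the highest doublet scores. Clusters 7 and 11 were set apart by cell cycle genes, cluster 8 (1.35%) by Lyz2, H2-Aa and S1pr1, and cluster 9 (0.89%) by Palld, Ramp3, Tnfrsf9 and Calca.

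In skin, cluster 1 (27.5%) was set apart by Ovol2, Cd2 and Hes1, cluster 2 (21.3%) by Hopx, Ccr6 and Ccr7, and cluster 6 (7.61%) by Il17f, Ccl5 and Cd7. Cluster 3 (20.2%) was set apart by Il2, Nfkbid, Hspa1a and Cd69, and had 3540.5 UMIs and 1236 genes per cell at the median. Cluster 4 (14.2%) was set apart by Il1rl1, Klrg1, Cxcl3 and Csf2. Its Il5 stood at 3720 CPM (3642 to 3799), against 351 to 1330 CPM in the other skin clusters, its Il13 at 2029 CPM against 353 to 695 CPM, and 10 of 19 type 2 effectors were at least 2-fold above the other skin cells. Il18r1 was spread over all 6 clusters, between 133 and 279 CPM. Cluster 5 (9.15%) was set apart by Birc5 and Hist1h2ap, with Mki67 at 413 CPM against 6.43 to 19.1 CPM in the others. Clusters in lung and skin were made separately, and their sizes were not compared between the libraries.

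**Figure D3:**
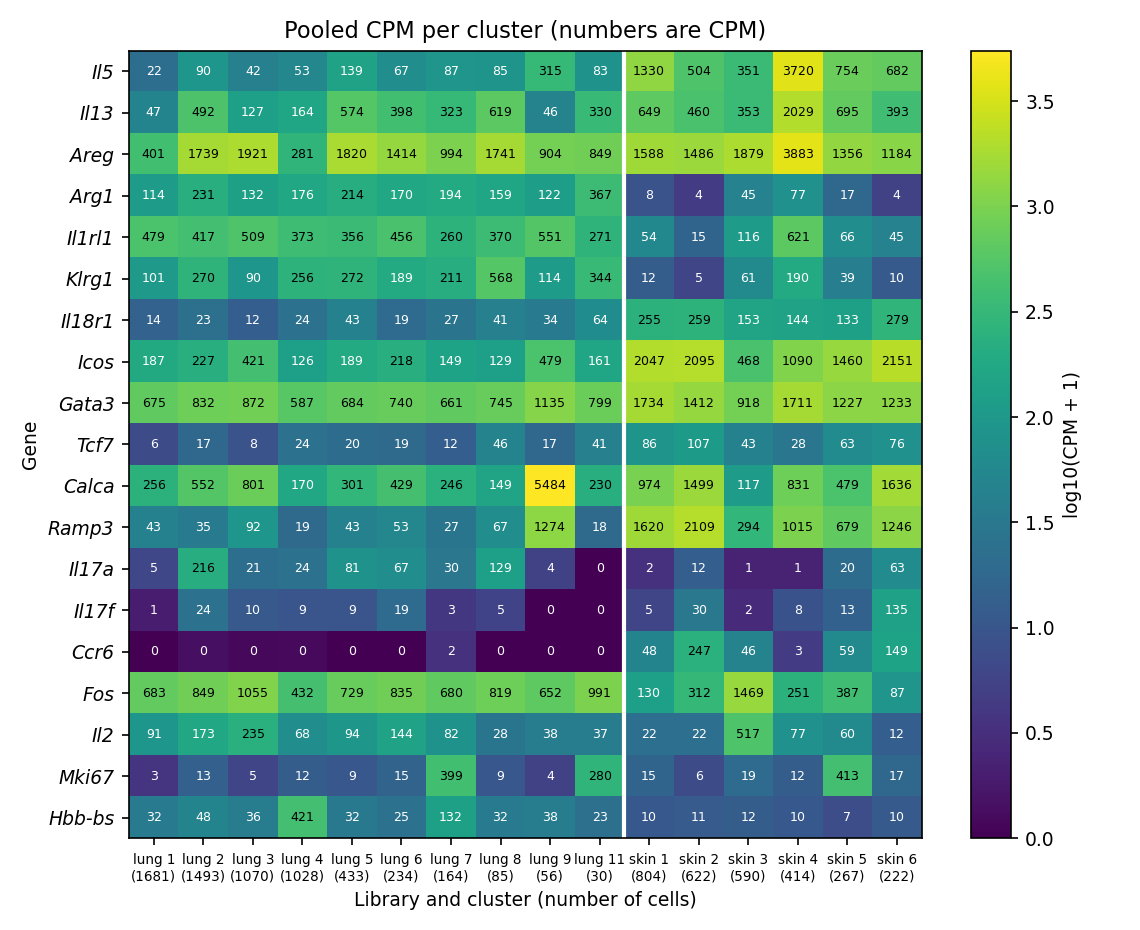
Each cell of the grid gives the pooled CPM of a gene (rows) in a cluster (columns, with the number of cells in brackets), coloured by log10 of CPM plus 1, with lung clusters left of the white line and skin clusters right of it. Il5 is highest in skin cluster 4 (3720 CPM), and in lung it is highest in cluster 9 (315 CPM), where Calca stands at 5484 CPM.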

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

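Tests of lung cells carried into skin, of skin cells carried into lung and of type 17 cells were fixed before their results were seen. The tests of doublets, of shallow or damaged cells, of dissociation and of free RNA were chosen after the result was seen. Intervals given with these tests are not counting intervals. Those of the place between the tissues come from resampling genes, as if genes were independent. That of the fold among deep cells comes from resampling cells. That of the Gata3 ratio divides the limits of the first share by the opposite limits of the second, and has no set level.

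A pair of clusters held genes of the other tissue. They were skin cluster 4, with 14.2% of the compared skin cells, and lung cluster 9, with 0.89% of the compared lung cells. Skin cluster 4 had Klrg1 at 190 CPM, close to the lung level of 197 CPM, and lung cluster 9 had Palld and Ramp3 at 231 and 1274 CPM, close to the skin levels of 229 and 1264 CPM. Cells carried over between the tissues would bring all their abundant genes, but the 60 genes at least 4-fold higher in lung sat a median of 0.0678 (0.0227 to 0.116) of the way from the other skin cells to the lung level in skin cluster 4, and the 116 genes at least 4-fold higher in skin sat 0.113 (0.0407 to 0.160) of the way in lung cluster 9, which argues against carried cells as the whole of either cluster. Doublets of other cells in the same library were expected to hold none of the raised genes above every other cluster of it. Raised genes above every other cluster were 6 of 12 in skin cluster 4 and 14 of 28 in lung cluster 9. This just meets a bound of 0.5 set after the result was seen. It cannot decide the question, since the genes were picked as raised in the cluster and doublets of high-expressing cells can exceed cluster means. The median depths of skin cluster 4 and lung cluster 9 were 5234.5 and 3843.5 UMIs, against 5126 and 4062.5 in the compared cells. Of their cells, 2.42% and 0% were among the highest doublet scores. These depths and scores show no sign of doublets. That these clusters may be ILC2 states shared between the tissues remains a hypothesis, with the tissue difference itself untested in 1 library each.

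Skin cluster 3 had immediate-early genes at a summed 27824 CPM against 14999 CPM in the other skin clusters, and 17 of 29 of these genes were at least 2-fold higher there, while its cells were the shallowest, at a median of 3540.5 UMIs, and had a median mitochondrial share of 3.41% against 2.57% to 2.95% in the other compared clusters. Shallow or damaged cells would lose the difference among deep cells with a low mitochondrial share, but there the fold was 1.96 (1.79 to 2.15) in 139 cells of the cluster against 1279 others, beside 1.86 over all cells, which argues against that explanation under a bound lowered after the fold over all cells was known, while the bound of 2 written first was not reached. A response to tissue dissociation cannot be told apart from stimulation in the animal, since both libraries came from single-cell suspensions and no undissociated sample was analysed here. Of the immediate-early genes, 12 were at least 2-fold higher in the left-out cells of other types too, and 10 were so in both, while their summed level in those cells, 14262 CPM, was below that of the other skin clusters. No biological explanation was tested for this cluster.

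Il17a, a cytokine of type 17 lymphocytes, stood at 216 CPM in lung cluster 2. Type 17 T cells or ILC3s with little Gata3 would have fewer cells with a UMI of it, but 91.2% of the 91 thinned cells with Il17a had a UMI of Gata3 against 84.4% of the other 1342 cells of the cluster, a ratio of 1.08 (0.967 to 1.17), which leaves ILC3s or T cells that express Gata3 open. Among genes chosen after their values were seen, Cd3e was detected in 0% of the cells with Il17a and 2.31% of the others, Cd3d in 1.10% and 0.298%, Cd3g in 46.2% and 54.9% and the ILC2 receptor Il1rl1 in 69.2% and 68.9%, and T cell receptor constant genes were not analysed here. Free RNA would give all clusters a like level. Yet cluster 2 stood 41.8-fold above cluster 1 at 5.17 CPM, the cluster with the lowest upper bound. The lowest level among clusters of 50 cells or more, 4.21 CPM in cluster 9, rests on 1 UMI. Il17a was the leading gene of cluster 2, and the clusters were made from the same counts, so part of this ratio is built in. The lung cluster with the next highest level of Il17a stood at 129 CPM. Il17a transcripts in lung ILC2s remain a hypothesis, and no biological explanation was tested.

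The odds ratio of Il13 with Il1rl1 went in opposite directions, 0.879 in lung and 1.75 in skin, but the lung interval ends close to 1 and the lung value turns to 1.13 with no thinning, and the difference was not tested. Cells outside the comparison held clear signals of other types. In skin they were 33 cells with endothelial genes, 25 cells with keratinocyte genes and 23 cells with fibroblast genes. In lung they were 30 cells with endothelial genes and also Scgb1a1, of airway club cells, at 123996 CPM, treated as a mixture. The barcodes that failed the filters, which no comparison used, still held Il5 at 83.0 CPM in lung and 955 CPM in skin.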

How the results depend on the processing

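Leaving out skin cluster 3 was chosen after seeing the data. The 36 named genes with a ratio tried under the alternatives were the key genes and the 10 with the largest ratio in each direction. The latter, picked for their size, could hardly fall under 2-fold, so their staying there shows little. Named list members outside these were not tried. Among them Rps27l, Cd74 and Chordc1, at 2.02-fold, 2.06-fold and 2.01-fold, have intervals that reach below 2-fold. All 36 kept their direction, and all 32 that were at least 2-fold apart stayed so. The 32 include Zbtb16 and Ctla4, which lay below 50 CPM in both libraries. Il5 lay between 4.13 and 4.39 (log2), Arg1 between -3.15 and -2.60, Il1rl1 between -1.74 and -1.24 and Il18r1 between 2.98 and 3.53. Others moved further, and of all their values 105 moved and 290 stayed: with only ILC2-like clusters Ccr6 went from 8.18 to 6.53, Itgae from 4.83 to 3.74, Ccr7 from 5.80 to 4.81, Palld from 4.82 to 3.95, Gimap3 from -4.08 to -3.17, Il17rb from -1.88 to -2.66 and Ctla4 from -2.59 to -4.49, and with other types kept Gimap6 went from -4.33 to -3.04. The counts of 357 genes higher in skin and 337 higher in lung were 571 and 777 with a 20 CPM minimum, 218 and 152 with 100 CPM, and 2291 and 2759 with at least 4 UMIs and no CPM minimum, since more or fewer genes enter; 528 were higher in lung with totals lacking mitochondrial and ribosomal protein genes, and centred on the median ratio 406 were higher in skin and 276 in lung. Of the list medians, 270 values stayed within their spread, 6 moved beyond it and 8 turned from outside the random range. The 270 and 6 include sign changes of the immediate-early, lipid metabolism, MHC class II, cytotoxic and sex-linked medians, and the immediate-early, lipid metabolism and cytotoxic lists left the random range in 2, 4 and 3 of 13 alternatives. The type 2 effector median of 0.35 turned to -0.31 with only ILC2-like clusters, -0.24 without skin cluster 3, -0.0594 with totals lacking mitochondrial and ribosomal protein genes and -0.0179 with a 50 CPM minimum for members. The S phase median of 0.47 turned to -0.63 without cycling cells, whose removal takes out dividing cells by construction, -0.20 with every cell weighted equally and -0.22 with thinned cells. The type 3 median of -0.98 turned to 0.66 with no minimum for members. Odds ratios crossed 1 without thinning for Il13 with Il1rl1 in lung (1.13), Il13 with Il18r1 in skin (1.27) and Mki67 with Il18r1 in skin (1.17), and at 1500 UMIs for Il13 with Il18r1 (1.02) and Arg1 with Areg (0.985) in skin. The number of clusters was 5 in lung at resolution 0.4 and 10 in skin at resolution 1.2. Except where stated, the cause was not tested. Shares of cells with a gene depend on depth, and 31 lung and 38 skin values of them moved while 33 and 42 stayed. No alternative replaces a second library per tissue.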

Other observations

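Some genes of lipid mediators and neuropeptides stayed under 50 CPM in both libraries, and so outside the rule of size. They differed between the libraries, in both directions. The list they belong to had a median log2 ratio of -0.24, within the random range, and a mean of -0.81. Alox5, which starts leukotriene synthesis, stood at 49.1 CPM in lung and 1.97 CPM in skin, its partner Alox5ap at 46.7 and 0.83 CPM, and Vipr2, a receptor of vasoactive intestinal peptide, at 36.4 and 0.54 CPM. Nmur1, the receptor of neuromedin U, stood at 8.49 and 0.36 CPM. Toward skin, S1pr1 stood at 4.58 CPM in lung and 25.2 CPM in skin, and Ptgdr2 had 1 and 37 UMIs. These genes were chosen after their values were seen. The peptide gene Calca was under 2-fold apart between the libraries, at 461 CPM in lung and 913 CPM in skin. Over the compared lung clusters it ranged from 149 CPM in cluster 8 to 5484 CPM (5190 to 5790) in cluster 9, and over the compared skin clusters from 117 CPM in cluster 3 to 1636 CPM in cluster 6.

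A small lung cluster and a small skin cluster stood out for antigen presentation genes, but neither was named ILC2-like, since their leading genes held a marker of macrophages or monocytes in lung and of ILC3s in skin, and 2 dendritic cell markers were also high in the lung cluster. In lung cluster 8, set apart by Lyz2, H2-Aa, H2-Ab1 and S1pr1, 6 of 8 measured MHC class II genes, 11 of 17 interferon response genes and 7 of 15 precursor or resting genes were at least 2-fold above the other lung cells. Klrg1 stood at 568 CPM and Il13 at 619 CPM in it. In skin cluster 6, set apart by Il17f, Ccl5 and Cd7, 6 of 8 MHC class II genes and 4 of 7 type 3 genes were at least 2-fold above the other skin cells, and Il17a stood at 62.8 CPM against 1.28 to 20.1 CPM in the other compared skin clusters. In lung cluster 5, 7 of 17 surface molecules and 9 of 19 type 2 effectors were at least 2-fold above the other lung cells, with Cd74 at 390 CPM. The growth factor gene Il2 stood at 517 CPM in skin cluster 3 and between 27.6 and 235 CPM over the compared lung clusters.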
